A study of Danio rerio with 9 samples.

How the data were processed

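The data were 9 one-colour oligonucleotide arrays of zebrafish hindbrain RNA. Per the labels, embryos of an islet-1 GFP transgenic strain were dissected at 19 to 20 hours post fertilization, the tissue of 8 to 10 embryos was dissociated with trypsin, RNA was isolated with a PicoPure kit, amplified with a RiboAmp HS kit and labelled with biotin. Groups were taken from the sample titles: normal r4, Hoxb1a-deficient r4 (morpholino-injected embryos) and normal r2, 3 samples each. The design text of the series assigns the replicate numbers to 3 separate experiments, the first of which held no r2 sample and the third 2. Whether normal embryos received a control injection, and whether embryos of 1 clutch were used within an experiment, is not given in the sources used here.

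The deposited table holds 16399 rows and 1 column per sample. Its values, which the authors deposited on a linear scale, were taken as a ratio of spot intensity to a constant per array, since every column has a median of 1.00 to 1.01, a minimum of 0.277 to 0.542 and no value at or below 0. The scanner, the image software, the treatment of background and the normalization are not given in the sources used here, and no detection flags or scanner files were used. Between 9 and 254 probes per array shared the array's highest value (107 to 190), which is read as saturation. Of the probes saturated on every array of a group (13 in normal r4, 9 in Hoxb1a-deficient r4 and 9 in r2) 0 were called in any comparison. The upper quartile ranged from 3.64 to 6.87.

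Probes were named through the platform annotation, with symbols updated for 6010 rows through Entrez gene IDs in a gene table of a later zebrafish assembly, which was used for names only and gave no coordinates. There were 6079 rows with 1 gene symbol, 74 with several and 10246 with none. A probe without a symbol is unnamed here and is not thereby without a gene. The 172 spots of 1 actb2 accession were left out of tests as control spots, which left 16227 probes for 5355 named genes. Where a gene had several probes (496 genes), the brightest stood for the gene in list tests. Values in the text come from a gene's only or brightest probe, apart from the first dnajb1b value. For gfap, hoxb3a, cldn7b, dlx3b and efna5a a second probe, below the array median in every group, showed no such difference.

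Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit on group means over all 9 arrays, eBayes with default settings, two-sided) on log2 of the deposited values, with Benjamini-Hochberg adjustment over the probes of a comparison and a threshold of 0.05. The design written before the data were examined used log2(value + 16) for linear intensities. That pseudocount assumed unscaled intensities. Once the values were seen to be ratios to the array median without zeros, 16 stood above the 75th percentile of every array, and no pseudocount was used. This choice was made after the scale of the values was seen, and the counts with log2(value + 16) are given beside the main ones: they are far smaller against r2, and 1 in place of 0 between Hoxb1a-deficient and normal r4. Array medians lay within 0.1 on the log2 scale, so no further normalization was applied. Values scaled to the array median meet this condition by construction, so it does not show that the distributions match. The upper quartile was 6.87 and 6.15 on the arrays of experiment 1 and 3.64 to 4.75 on the others. The median log2 fold change of all probes was 0.08 between r2 and r4, and 0.00 after quantile normalization.

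The replicate numbers pair the samples, since the design text ties each number to an experiment. Deviations of same-numbered r4 and Hoxb1a-deficient r4 arrays from their group means correlated with 0.892, 0.730 and 0.683 across probes, and those of differently numbered arrays with -0.781 to 0.504. A fit with the experiment as a fixed block was therefore set beside the unblocked one, and differences within experiments were computed for named genes and lists. For r2 this fit rests on experiments 2 and 3. The 2 r2 samples of experiment 3 correlated with r = 0.991 and were kept as separate samples, with their mean as an alternative.

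Named genes were chosen by a rule fixed before the data were examined: hoxb1a and prickle1b always, list members past the test, the members of a list with the largest folds (at most 4) where they did not pass, and the 12 largest increases and decreases past the test with 1 symbol, a mean above the array median in the higher group and no overlap between groups. Where fewer than 10 passed, the 10 with the lowest p were named as not past the test. Probes 4651 and 4686, dab2, gfap and ctslb were chosen after their values were seen. Groups did not overlap for 2.08%, 8.76% and 10.5% of probes in Hoxb1a-deficient r4 against r4, r2 against r4 and Hoxb1a-deficient r4 against r2. For unrelated arrays chance would give 10%. The arrays here share experiments, so 10% does not measure what unchanged groups on them would give.

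The 26 gene lists were fixed before the data were examined. They covered Hox genes and cofactors, segment genes, r4 genes, midbrain boundary genes, Fgf and retinoic acid signalling, cranial motor neurons, planar polarity, progenitors, neurons, sensory ganglia, ear, neural crest, floor plate and notochord, skin, muscle, heart, blood, endothelium, yolk and endoderm, eye and forebrain, the p53 response, the cell cycle, immediate early and stress genes and reference genes. They were tested with camera (preset correlation 0.01, and an estimated correlation beside it) and with fry. No gene coordinates were used.

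The tests were run on simulated data with the real probe means, experiment differences and residual spread, with 200 of the 16227 probes changed in each of 10 data sets, 100 by a log2 change of 1 and 100 by 2. The changed probes were drawn from those with a mean above the median of all tested probes. The shares recovered hold for such probes and for that number of changes. Without the block, a log2 change of 2 was recovered in 61.9%, 60.7% and 59.9% of changed probes for Hoxb1a-deficient r4 against r4, r2 against r4 and Hoxb1a-deficient r4 against r2, and a log2 change of 1 in 2.3%, 1.8% and 2.5%. With the block these were 99.9%, 99.9% and 99.7%, and 93.4%, 89.8% and 90.9%, with 12.2, 14.5 and 12.1 unchanged probes called per set against 0 without the block. On 5355 simulated genes camera found the 1 moved list in 10 of 10 sets in each comparison and called on average 0.3, 3.3 and 4.5 of the other lists. Its calls against r2, where experiment 1 is missing, may thus include lists moved by the experiments alone. The simulated experiment differences were estimated without the groups and can hold part of the r2 differences. Which real calls are affected was not tested. Alternatives covered normalization, pseudocounts, dim probes, blocks, eBayes settings, array weights, thresholds and single arrays left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.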

Results

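Microarray measurements were made on hindbrain tissue of zebrafish embryos carrying an islet-1 GFP transgene, at 19 to 20 hours post fertilization. Each sample was a thick cross-section of hindbrain around 1 rhombomere, the segmental unit of the developing hindbrain, taken from 8 to 10 embryos. The 9 arrays fell into 3 groups of 3: rhombomere 4 (r4) of normal embryos (normal r4), r4 of embryos injected with a Hoxb1a morpholino (Hoxb1a-deficient r4), and rhombomere 2 (r2) of normal embryos (normal r2), a second tissue used as a source without Hoxb1a. The arrays came from 3 experiments: experiment 1 held r4 and Hoxb1a-deficient r4, experiment 2 held 1 sample of each tissue, and experiment 3 held 1 r4, 1 Hoxb1a-deficient r4 and 2 r2 samples (3a and 3b). Values are spot intensities divided by a constant that brings each array's median to about 1, and are given below as multiples of the array median. A probe at or below 1 lies among the dimmer probes of the array, where background was not separated from signal. The 16227 probes tested included 5907 with 1 gene symbol. The number of arrays limits the precision, and p-values measure the spread between these 9 tissue samples. Without a block that spread includes differences between experiments. For r2, n = 3 counts samples 3a and 3b of experiment 3 separately, and stands for 2 experiments.

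The level of hoxb1a, the Hox gene that marks r4, was examined first in every array. Its probe read 3.02, 2.42 and 1.88 in normal r4 of experiments 1, 2 and 3, and 3.17, 1.52 and 1.51 in Hoxb1a-deficient r4. In normal r2 it read 0.774, 0.590 and 0.567, below the median of every r2 array, so that the fold against r2 understates the difference. The hoxb1a transcript was lower in r2 than in r4 by a log2 fold change of -1.91 ± 0.32 (SE, n = 3 per group, adjusted p = 0.0285) and did not pass the test between Hoxb1a-deficient and normal r4 (-0.30 ± 0.32, adjusted p = 1.00). A morpholino that blocks translation leaves the transcript in place, and the labels do not state which kind was used, so the probe checks the r2 label but not the knockdown. The r2 call on hoxb1a was lost without any 1 of the 6 arrays compared (adjusted p from 0.0628 without normal r4 replicate 3 to 0.178 without normal r2 replicate 3b), and held with the experiment as a replicate block (adjusted p = 0.00137).

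**Figure D1:**
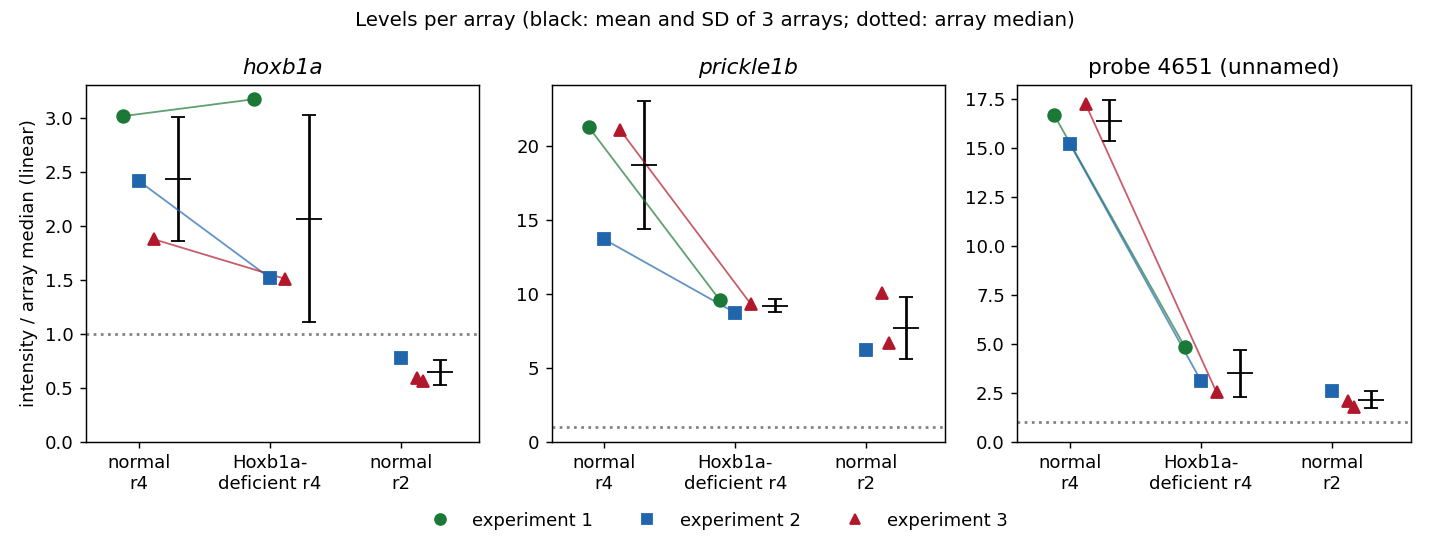
Intensity of the probes of hoxb1a and prickle1b and of the unnamed probe 4651, as multiples of the array median on a linear axis from 0, for each of the 9 arrays. Colours and symbols mark the experiment, lines join the r4 and Hoxb1a-deficient r4 arrays of an experiment, black marks give the mean and SD of 3 arrays and the dotted line the array median. prickle1b and probe 4651 were lower in Hoxb1a-deficient r4 than in r4 in each of the 3 experiments, and hoxb1a was below the array median in r2 only.

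Hoxb1a-deficient r4 was compared with normal r4 to find transcripts that depend on Hoxb1a. The gene prickle1b, which encodes a planar polarity protein needed for the migration of facial motor neurons, measured 18.7 ± 4.34 in normal r4 (SD, n = 3), 9.21 ± 0.450 in Hoxb1a-deficient r4 and 7.68 ± 2.095 in normal r2. Its log2 differences between Hoxb1a-deficient and normal r4 were -1.15, -0.65 and -1.18 in experiments 1, 2 and 3. The chemokine gene cxcl12b measured 2.35 ± 0.447 in r4, 5.74 ± 1.27 in Hoxb1a-deficient r4 and 6.15 ± 1.06 in r2, and timp2b, an inhibitor of metalloproteinases, 4.17 ± 1.67, 10.2 ± 1.34 and 2.48 ± 0.461. None of these passed limma's test: 0 probes did at an adjusted p under 0.05, with 82 at an unadjusted p under 0.05, and 1 did with log2(value + 16). The 82 are 0.505% of the probes, far below the share of 0.05 that unchanged groups of unrelated arrays would give. This fit counts differences between experiments as spread. In simulated sets with 200 changed probes it recovered 2.3% of those changed by 1 on the log2 scale and 61.9% of those changed by 2. Its 0 calls thus do not show that no probe changed. The log2 fold changes were -0.99 ± 0.26 for prickle1b, 1.28 ± 0.26 for cxcl12b and 1.35 ± 0.30 for timp2b (SE, adjusted p = 1.00 each).

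With the experiment as a replicate block, which removes the differences between experiments, 2 probes fell and 0 rose. An unadjusted p under 0.05 was reached by 932 (5.74% of the probes), little above the share of 0.05 for unchanged probes. In simulated sets with 200 changed probes this fit called on average 12.2 unchanged ones, beside 93.4% and 99.9% of those changed by 1 and 2. The changed probes were drawn from the brighter ones. The adjustment allows more calls, of changed and of unchanged probes, where more probes change. Neither 12.2 nor the shares recovered thus carry over to a fit with 2 calls. Both probes lack a gene symbol. Probe 4651 fell by 2.28 ± 0.19 on the log2 scale (SE, adjusted p = 0.0102), from 16.4 ± 1.05 in r4 to 3.49 ± 1.19 in Hoxb1a-deficient r4 (SD, n = 3), and measured 2.16 ± 0.417 in r2. Probe 4686 fell by 1.90 ± 0.18 (adjusted p = 0.0193), from 43.4 ± 12.4 to 11.6 ± 3.32, and measured 38.0 ± 4.71 in r2. Their log2 differences between Hoxb1a-deficient and normal r4 were -1.79, -2.28 and -2.77 for probe 4651 and -1.81, -1.51 and -2.39 for probe 4686 in experiments 1, 2 and 3. Both calls were lost with the replicate block and log2(value + 1) (0 probes) and with the block and experiment 1 left out (0 probes), where 7 arrays remained. Other settings with a block called more probes. These were 5 with quantile normalization added, 11 with a trended, robust eBayes, and 9 (5 higher, 4 lower) with the experiment as a random block. In the same blocked fit prickle1b had an adjusted p of 0.274, cxcl12b 0.231 and timp2b 0.277. Over 28 other settings cxcl12b passed limma's test in 2 (lowest adjusted p = 0.0452), and prickle1b and timp2b in 0.

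Other named genes with the lowest p in this comparison did not pass either fit. The glutamate transporter slc1a2b measured 14.6 ± 2.27 in r4 and 8.07 ± 2.24 in Hoxb1a-deficient r4 (blocked adjusted p = 0.151), and lrrn1 46.0 ± 3.48 and 25.4 ± 6.39. The log2 fold changes of tbc1d14, tnrc6c1 and pcbp4 were -0.78 ± 0.24, -0.67 ± 0.24 and -1.003 ± 0.38, and that of ptx3a was 0.63 ± 0.22, and ptx3a and tbc1d14 lay near the array median in both groups. The heat shock cochaperone gene dnajb1b had 0.68 ± 0.26 on 1 probe and 0.09 on its brighter probe.

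Of the 26 gene lists fixed beforehand, none differed between Hoxb1a-deficient and normal r4 with camera (lowest adjusted p = 0.510). No member of any list passed the test, over all probes or adjusted over the list alone. In the blocked fit, adjusted over the list alone, prickle1b was lower in 2 lists (16 planar polarity and neuron migration genes, and 16 genes reported in rhombomere 4 or downstream of Hoxb1). The radial glia genes fabp7a and gfap were lower among 33 neural progenitor genes, and dab2 among 16 endothelial genes. fabp7a measured 9.47 ± 11.3 in r4 and 4.54 ± 5.15 in Hoxb1a-deficient r4, with log2 differences of -1.10, -0.64 and -1.21 in the 3 experiments, and gfap 36.1 ± 32.1 and 19.5 ± 13.4, with -0.85, -0.38 and -1.14. The 12 measured p53 response genes, which can respond to morpholinos, had a median log2 fold change of 0.02 (camera adjusted p = 0.520). The 42 Hox genes, 19 cranial motor neuron genes and 8 segment genes of rhombomeres 3 and 5 to 6 had medians of 0.03, -0.02 and -0.11. The number of lists called depended on single arrays: 8 without Hoxb1a-deficient r4 replicate 1, 6 without normal r4 replicate 2, 3 without normal r4 replicate 3 and 1 without normal r4 replicate 1. Leaving out any of these arrays also leaves its experiment in only 1 of the groups compared, and the cause of these counts was not tested.

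A count without a test asked which probes changed by at least 1.5-fold in each of the 3 experiments. There were 20 lower and 8 higher probes. With the sign of experiment 1, 2 or 3 turned, 1, 16 and 2 probes were lower and 5, 0 and 5 higher. The named probes among the lower ones were prickle1b, slc1a2b, fabp7a, tnrc6c1 and the neurofilament gene nefma (2.00 ± 0.445 in r4, 1.28 ± 0.261 in Hoxb1a-deficient r4), and the higher ones cxcl12b and timp2b. At 2-fold the counts were 5 and 4, against at most 0 and 2 with a turned sign, and with log2(value + 16) at 1.5-fold they were 3 and 1. Without a pseudocount 198 probes were lower and 78 higher at 1.2-fold, against up to 336 and 106 with a turned sign.

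Normal r2 was compared with normal r4 as a second tissue, low in hoxb1a transcript. Higher in r2 was otx2b, a homeobox gene of the forebrain and midbrain (1.08 ± 0.362 in r4, 12.7 ± 8.10 in r2, SD, n = 3; log2 fold change 3.37 ± 0.46, SE, adjusted p = 0.00749). So was fgf8a, a signal of the boundary between midbrain and hindbrain (1.08 ± 0.328 and 4.80 ± 0.890; 2.19 ± 0.31, adjusted p = 0.00907). The sections were thick, and whether otx2b and fgf8a came from r2 itself or from tissue beside it was not tested. Lower in r2 were hoxb3a and hoxa3a, Hox genes of the hindbrain behind r4 (log2 fold changes -4.17 ± 0.76 and -2.59 ± 0.29, adjusted p = 0.0412 and 0.00262, both below the median on every r2 array). So was egr2b, the transcription factor of rhombomeres 3 and 5 (129 ± 20.4 in r4 and 41.6 ± 14.8 in r2; -1.70 ± 0.30, adjusted p = 0.0363). The otolith gene otop1 and the otic placode gene dlx4b were lower by -4.32 ± 0.45 and -3.998 ± 0.41 (adjusted p = 0.00163 and 0.00161). In all, 22 probes were higher and 72 lower in r2. Of the 72, 23 were below the median on every r2 array, otop1, hoxb3a and hoxa3a among them, and their folds understate the difference.

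Other increases in r2 past the test were gch2, a pteridine synthesis gene of pigment cells (log2 fold change 2.36 ± 0.22), the ephrin gene efna5a (2.302 ± 0.31) and pdzrn3b (2.098 ± 0.33). Smaller ones were iqgap2 (0.892 in r4, 2.55 in r2), cxcl12b (1.39 ± 0.26), arhgap28 (1.33 ± 0.25) and the purine synthesis gene atic (1.19 ± 0.22). Named decreases beside otop1, hoxb3a and dlx4b, whose order is not fixed where r2 lies near or below the median, were the claudin gene cldn7b (-4.47 ± 0.57), ahcyl1 (-4.11 ± 0.38), b3gnt7l (-3.80 ± 0.45), the claudin gene cldn3c (-3.72 ± 0.49) and the tetraspanin gene cd9b (-3.67 ± 0.29). Others were the adhesion gene epcam (-3.43 ± 0.46), the claudin gene cldnj (-3.34 ± 0.28), znf385a (-3.25 ± 0.46) and the tenascin gene tnn (-3.25 ± 0.46). prickle1b had a log2 fold change of -1.29 ± 0.26 (SE, adjusted p = 0.0741) and passed with the replicate block (-1.28, adjusted p = 0.0107).

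By list, 6 of the 22 otic vesicle genes fell in r2 and 0 rose (7 and 0 adjusted over the list alone): dlx4b, dlx3b, epcam, six4b, gata3 and eya1. Of 8 segment genes of rhombomeres 3 and 5 to 6, 3 fell (5 adjusted over the list alone), namely hoxb3a, hoxa3a and egr2b. Of 16 genes reported in rhombomere 4 or downstream of Hoxb1, 4 fell, hoxb1a, gata3, sfrp2 and egr2b, and fgf8a rose (6 lower and 1 higher adjusted over the list alone). Among 9 cranial sensory ganglion genes 3 fell (4 adjusted over the list alone), neurod1 (47.5 ± 19.0 in r4, 5.54 ± 0.581 in r2), six4b and eya1, and among 18 skin and periderm genes 2 fell (5 adjusted over the list alone), cldn3c and epcam. Of 19 midbrain, isthmus and rhombomere 1 genes, otx2b and fgf8a rose (4 adjusted over the list alone). Lists overlap: epcam counts as otic and as epidermal, and eya1 and six4b as otic and as ganglion genes.

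Camera called 9 lists between r2 and r4. The segment genes of rhombomeres 3 and 5 to 6 (adjusted p = 5.61e-07) and the otic vesicle genes (9.24e-07) were also called with an estimated correlation (adjusted p = 0.0439 each). The other 7 were not: the genes of rhombomere 4 or downstream of Hoxb1 (lower, adjusted p = 0.067 with an estimated correlation), midbrain, isthmus and rhombomere 1 genes (higher, 0.0674), and skin and periderm genes (lower, 0.102). Nor were cranial sensory ganglion genes (lower, 0.144), immediate early and stress genes (lower, 0.307), endothelial genes (higher, 0.307) and heart genes (higher, 0.773). The heart genes were called in only 12 of 26 other settings and had the opposite direction, without a call, in 2. They lost their call with the replicate block (adjusted p = 0.431), and the 42 Hox genes gained one as lower (0.0148). No list, 0 of 26, was called with the replicate block and an estimated correlation together. No member of the heart, endothelial or immediate early lists passed the test (33 immediate early genes, 2 lower adjusted over the list alone; 16 endothelial genes, 1 higher and 1 lower). The median of the immediate early genes was -0.51 over all arrays but -0.15 and -0.08 within experiments 2 and 3.

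Among the lists that camera did not call in this comparison, 6 had members past the test. Of 42 Hox genes hoxb3a, hoxa3a and hoxb1a fell. Of 19 cranial motor neuron genes slc18a3a, the vesicular acetylcholine transporter, fell from 3.62 ± 0.709 to 0.784 ± 0.139 (log2 fold change -2.20 ± 0.23, adjusted p = 0.00161). The retinoic acid receptor gene raraa was the 1 of 14 retinoic acid pathway genes that fell (-1.40 ± 0.24), neurod1 the 1 of 47 neurogenesis and neuron genes, and dlx5a the 1 of 22 eye and forebrain genes (-2.02 ± 0.33). Of 35 neural crest and pharyngeal genes gch2 rose and dlx5a fell. No member passed among Hox cofactors (12 measured), Fgf signalling targets (13), planar polarity and neuron migration genes (16), neural progenitor genes (33), floor plate and notochord genes (24), skeletal muscle genes (25), blood genes (22), yolk, endoderm and hatching gland genes (17), p53 response genes (12), cell cycle genes (41) and reference genes (11).

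**Figure D2:**
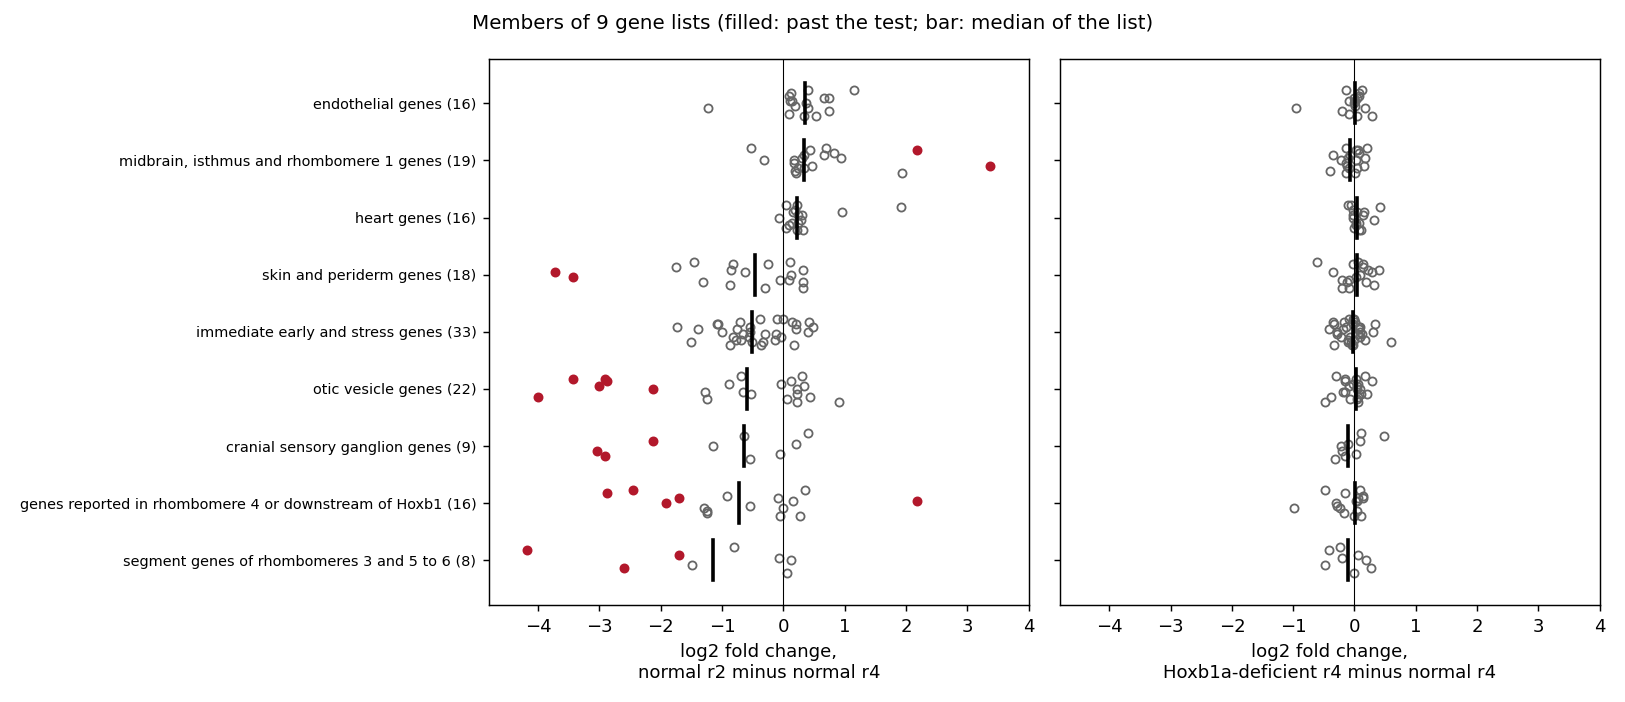
Log2 fold changes of the members of the 9 gene lists that camera called between normal r2 and normal r4 (number measured in parentheses), for r2 minus r4 on the left and Hoxb1a-deficient r4 minus r4 on the right. Each circle is 1 gene, filled where it passed the test, and black bars are list medians. On the left 6 otic vesicle genes at -2.12 to -3.998 are filled, and no gene is filled on the right.

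The r2 comparison rested on unequal experiments, since experiment 1 held no r2 sample. In the blocked fit, with the experiment as a replicate block, 124 probes were higher and 152 lower, and all 94 calls were shared in the same direction. Quantile normalization gave 54 higher and 108 lower. The count was 52 without normal r2 replicate 2, 44 without normal r4 replicate 3, 33 without normal r2 replicate 3a and 42 without normal r2 replicate 3b. It was 41 with the 2 r2 samples of experiment 3 averaged and 4 with log2(value + 16). With log2(value + 64) it was 4, of which 3 were higher and 1 lower, so the balance of directions turned there. The 90th percentile of every array lay below 64 (16.2 to 29.7). This setting thus shrinks nearly all differences, and its 4 calls do not measure the balance. Of 28 other settings, the calls between r2 and r4 were lost in 19 for egr2b, 18 for cxcl12b, 17 for arhgap28, 14 for eya1, 13 for hoxb3a and atic, 12 for dlx5a and sfrp2, 11 for iqgap2, pdzrn3b and raraa, and 10 for dlx3b and hoxb1a.

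The probes that differed between r2 and r4 were then followed in Hoxb1a-deficient r4. The 72 lower probes had a median log2 fold change of -2.39 in r2 and -0.15 in Hoxb1a-deficient r4, with an interquartile range of -0.41 to 0.04 in the latter. Their median in Hoxb1a-deficient r4 was -0.41, 0.44 and -0.53 in experiments 1, 2 and 3. The 22 higher probes had medians of 1.98 in r2 and 0.00 in Hoxb1a-deficient r4. In 2 of the 72 and 1 of the 22 the change in Hoxb1a-deficient r4 reached 50% or more of that in r2, among them probe 4651 and cxcl12b. Both changes are taken against the same normal r4 arrays, so part of a shared change can come from those arrays.

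**Figure D3:**
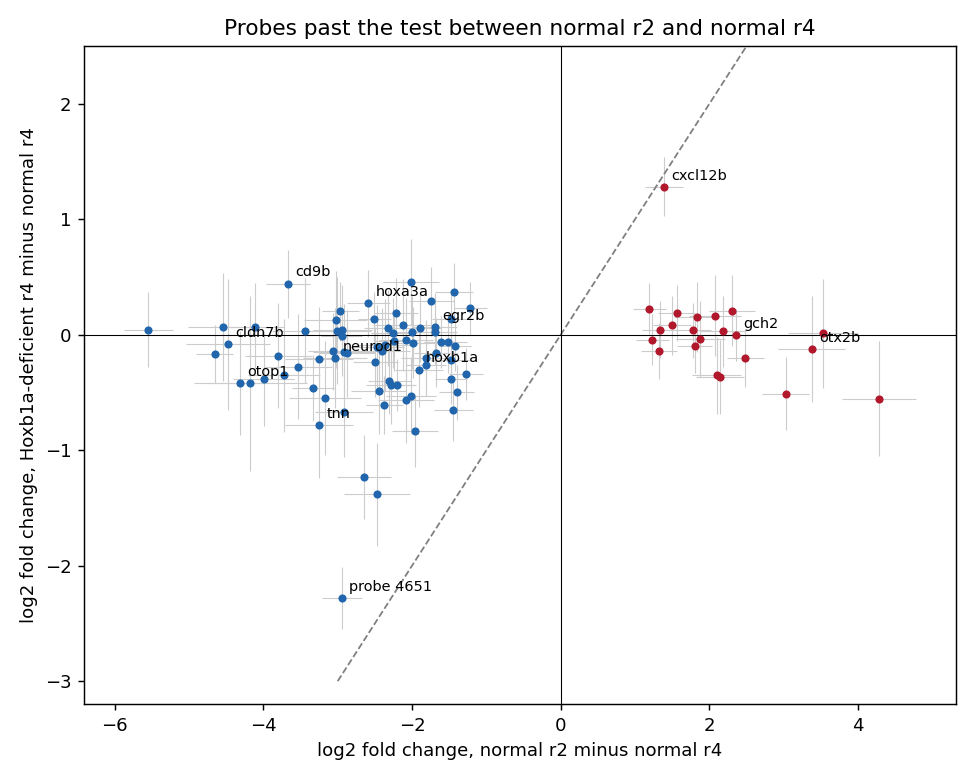
Log2 fold change of the 94 probes past the test between normal r2 and normal r4 (horizontal axis, 72 lower in blue and 22 higher in red), against their log2 fold change between Hoxb1a-deficient and normal r4 (vertical axis). Grey bars are standard errors and the dashed line marks equal changes. Both axes subtract the same normal r4 arrays, so spread between these arrays moves a probe in the same direction on both. Most probes lie near 0 on the vertical axis, with a median of -0.15 for the lower and 0.00 for the higher probes, and cxcl12b and probe 4651 lie near the dashed line.

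Both tissues were tested together against normal r4, as the mean of the Hoxb1a-deficient r4 and r2 groups minus the r4 group. In that contrast 4 probes fell and 0 rose: cldnj (log2 fold change -1.90 ± 0.25, SE, adjusted p = 0.0466), probe 4651 (-2.61 ± 0.23, adjusted p = 0.00303) and 2 further unnamed probes. For cldnj and the 2 unnamed probes the change lay in r2, with log2 fold changes of -3.34, -5.55 and -4.66 there and -0.46, 0.04 and -0.17 in Hoxb1a-deficient r4. The count was 67 (11 higher, 56 lower) with the replicate block, 28 with quantile normalization and 1 with log2(value + 16), and without single arrays it ranged from 2 to 12.

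No probe passed limma's test in the same direction in Hoxb1a-deficient r4 and in r2 against normal r4, with 18 lower and 6 higher in both at an unadjusted p under 0.05. Without the block 1 probe was lower in both with log2(value + 16), log2(value + 64), array weights or experiment 1 left out. With the replicate block 1 probe was lower in both, probe 4651 (-2.28 in Hoxb1a-deficient r4 and -2.77 in r2, adjusted p = 0.0102 and 0.000206). That count was 0 with the block and log2(value + 1) and 0 with the block and experiment 1 left out. It stands against 0.0187 for independent lists of these lengths and a highest count of 1 in 100 simulated sets of unchanged groups that shared the r4 arrays. Independent lists leave the shared r4 arrays out, and the simulated groups have almost no calls to share (on average 0.02 lower in both). Neither value thus shows what the shared arrays add. Across all 16227 probes, which are not independent, the fold changes of the 2 comparisons had a Pearson correlation of 0.252, while unchanged groups sharing the r4 arrays gave a mean of 0.501. The covariance was 0.0206 against a simulated 0.0555. The unblocked simulation leaves out the experiments, which r4 and Hoxb1a-deficient r4 share and r2 only in part. Its 0.501 and 0.0555 are thus no measure of what unchanged groups on these arrays would give. With the replicate block the correlation was 0.170 against a simulated 0.465, and the covariance 0.0112 against 0.0131.

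Hoxb1a-deficient r4 was set against normal r2 to compare the 2 tissues that stand for missing Hoxb1a with each other. The claudin gene cldn7b measured 35.1 ± 17.3 in Hoxb1a-deficient r4 and 1.55 ± 0.439 in r2 (SD, n = 3; log2 fold change 4.39 ± 0.57, SE, adjusted p = 0.00789). The levels of cd9b were 29.4 ± 6.40 and 1.69 ± 0.299 (4.11 ± 0.29, adjusted p = 0.000213) and those of otop1 11.8 ± 6.51 and 0.723 ± 0.0415 (3.90 ± 0.45, adjusted p = 0.00393). otx2b was lower by -3.50 ± 0.46 (adjusted p = 0.00815) and fgf8a by -2.16 ± 0.31 (adjusted p = 0.0118). prickle1b did not pass (0.30 ± 0.26, adjusted p = 0.996). hoxb1a had a log2 fold change of 1.60 ± 0.32 (adjusted p = 0.077) and passed with the replicate block (1.30 ± 0.16, adjusted p = 0.00425). In all 62 probes were higher and 28 lower.

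Further increases in Hoxb1a-deficient r4 over r2 past the test were ahcyl1 (log2 fold change 4.18 ± 0.38), dlx4b (3.62 ± 0.41), b3gnt7l (3.62 ± 0.45), epcam (3.47 ± 0.46), and cldn3c (3.37 ± 0.49). So were the protease inhibitor gene spint2 (3.16 ± 0.25), dlx3b (3.04 ± 0.46), znf385a (3.04 ± 0.46) and the phospholipase gene plcd1b (2.97 ± 0.39). Decreases were pdzrn3b (-2.45 ± 0.33), gch2 (-2.36 ± 0.22), efna5a (-2.09 ± 0.31), cnpy1, an Fgf pathway gene of the midbrain boundary (-2.08 ± 0.39), the growth factor gene vegfab (-2.00 ± 0.33) and iqgap2 (-1.42 ± 0.26). Of the 22 otic vesicle genes 6 were higher (7 adjusted over the list alone), and of 9 cranial sensory ganglion genes 3 (4). Also higher were, of 8 segment genes of rhombomeres 3 and 5 to 6, egr2b and hoxa3a (3), of 18 skin and periderm genes 2 (4), and of 16 genes reported in rhombomere 4 or downstream of Hoxb1, gata3 and egr2b, with fgf8a lower. Of 19 midbrain, isthmus and rhombomere 1 genes 3 were lower (6 adjusted over the list alone). slc18a3a was higher by 1.77 ± 0.23 (adjusted p = 0.00764).

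Camera called 9 lists here too. In the order of their adjusted p with an estimated correlation, with which none was called, these were otic vesicle genes (higher, 0.0615), segment genes of rhombomeres 3 and 5 to 6 (higher, 0.0629), and midbrain, isthmus and rhombomere 1 genes (lower, 0.0816). Next were skin and periderm genes and genes of rhombomere 4 or downstream of Hoxb1 (higher, 0.0823 each), cranial sensory ganglion genes (higher, 0.153), floor plate and notochord genes (higher, 0.227), endothelial genes (lower, 0.329) and immediate early and stress genes (higher, 0.341). The floor plate and notochord genes (adjusted p = 0.0683) and the endothelial genes (0.101) lost their call with the replicate block, and the Hox genes (0.00136) and the eye and forebrain genes (0.00327) gained one as higher. Neither gain held with an estimated correlation (adjusted p = 0.589 and 0.368). The floor plate and notochord genes were called in 13 of 27 other settings and the endothelial genes in 19 of 26. The median of the immediate early genes was 0.43 over all arrays but 0.59 and -0.06 within experiments 2 and 3.

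Of the 72 probes lower in r2 than in r4, 56 were also called against Hoxb1a-deficient r4, and of the 22 higher probes 19 were. Independent lists would share 0.275 and 0.038. Simulated unchanged groups sharing the r2 arrays have almost no calls to share (at most 0 and 0 in 20 sets), so the counts do not show what the shared arrays add. The fold changes of r2 against the 2 r4 tissues correlated with r = 0.883 across probes (simulated 0.498), with a covariance of 0.149 against a simulated 0.0551. The simulation leaves out the experiments, which both r4 tissues share and r2 only in part. The correlation was 0.836 with the replicate block (simulated 0.567) and the covariance 0.099 against 0.0171. With the replicate block the split was 142 higher and 217 lower, with all 90 calls shared in the same direction, and with quantile normalization 109 and 77. The count was 56 without normal r2 replicate 2, 31 without replicate 3a, 27 without replicate 3b, 35 without Hoxb1a-deficient r4 replicate 2 and 52 without its replicate 3. It was 30 with the r2 samples of experiment 3 averaged and 5 with log2(value + 16). With log2(value + 64) it was 4, with 0 higher and 4 lower, so no increase in Hoxb1a-deficient r4 over r2 kept its call there. A pseudocount above the 90th percentile of every array shrinks nearly all differences, so these 4 calls do not measure the balance of directions. Calls were lost in 15 of 28 other settings for egr2b, 14 for iqgap2, 12 for eya1 and 10 for cnpy1 and vegfab.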

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

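Apart from the counts of other splits of the samples, every test in this part was chosen after the result it examines had been seen. The result that drew attention came from spots outside the comparisons. The array carries 172 spots of 1 actb2 sequence, which were left out of all tests. The same 56 of them read below the array median on both arrays of experiment 1, and on each of the other 7 arrays 0 did. The remaining spots stayed above it, and the medians of all 172 were 42.8 in normal r4 and 28.3 in Hoxb1a-deficient r4 of experiment 1. A first principal component with 59.9% of the variance also set the 2 arrays of experiment 1 apart, and arrays of the same experiment and different groups correlated with a median r of 0.982 (9 pairs), against 0.964 for arrays of the same group and different experiments (8 pairs).

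Another print or batch of arrays in experiment 1 stays open. The 56 spots prompted that explanation and so do not test it, and they do not separate the print from hybridization or scanning on another day. No biological explanation was tested. In the fits with the replicate block this difference is removed from the comparison of Hoxb1a-deficient with normal r4, while r2, which experiment 1 lacks, is compared with r4 within experiments 2 and 3 only.

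The second pattern is the set of 72 probes lower in normal r2 than in normal r4, with otop1, dlx4b, epcam and the claudins. The tables argue against 2 explanations of the set as a whole. If loss of Hoxb1a were the cause, the probes would fall in Hoxb1a-deficient r4 by at least 50% of their fall in r2, and their median there was -0.15 against -2.39 in r2, in embryos whose knockdown the arrays do not check. If the missing r2 array of experiment 1 were the cause, most calls would end without that experiment, and 64 of the 72 were still made. What stays open is the tissue itself. Of the 8 measured segment genes of rhombomeres 3 and 5 to 6, 5 had a mean above 2 array medians in the r4 sections (egr2b at 129, hoxb3a at 16.3, epha4a at 14.4, hoxa3a at 3.63 and epha4b at 2.07). Of these, egr2b (41.6) and epha4a (4.63) were above 2 in the r2 sections too, and epha4b was above 2 only in experiment 1 (1.92 and 1.54 in experiments 2 and 3). The mean of hoxb3a was carried by experiment 1 (34.9, against 6.76 and 7.29), but hoxb3a and hoxa3a were above 2 on every r4 array and below 1 on every r2 array. The thick sections around r4 may thus have held segments behind r4, and with them tissue of the ear, which lies beside rhombomeres 5 and 6. A difference between rhombomeres 2 and 4 themselves stays open and was not tested apart from this.

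Of the 10 splits of the 6 r2 and r4 arrays into 3 and 3, 1 gave as many called probes, the real one (94, highest other 0), and 4 gave as many gene lists (9, highest other 11). For Hoxb1a-deficient r4 against r2 these were 1 of 10 (90, highest other 0) and 2 of 10 (9, highest other 9). With 10 splits no share under 0.05 can be reached. For the gene lists 4 and 2 of the 10 splits reached the real number, so the number of lists was no larger than other groupings of the arrays gave.

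The third pattern is the 20 probes at least 1.5-fold lower in Hoxb1a-deficient r4 in each of the 3 experiments, with prickle1b among them. Less ear and epithelial tissue in the Hoxb1a-deficient sections would lower the 72 probes of the second pattern in each experiment, and their median was 0.44 in experiment 2 (interquartile range 0.06 to 0.63), which argues against it as the cause in all 3. Unrelated differences between the experiments stay open. With the sign of experiment 1, 2 or 3 turned, 1, 16 and 2 probes met the same condition, against 20 for the real signs. Unrelated experiments would give similar counts whichever sign is turned. The 16 are probes that fell in experiments 1 and 3 and rose in experiment 2, a shift that those 2 experiments shared, so the count does not show what unrelated experiments give and does not decide. At 2-fold the count was 5 against 0 with any sign turned. At 1.2-fold it was 198, against 48, 336 and 41 with the sign of experiment 1, 2 or 3 turned. An effect of Hoxb1a on these probes stays open.

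Between Hoxb1a-deficient and normal r4 all 10 splits gave as many called probes (0, highest other 0). With the replicate block 1 of the 4 splits that part the 3 pairs did, the real one (2, highest other 0). These 4 splits are too few for a share under 0.05. Without the block the real split gave 0 gene lists and other splits up to 11. Splits with both arrays of experiment 1 in the same group gave 7 to 11 lists, and splits that parted them 0 to 2. For r4 against the other 6 arrays in a fit of 2 groups, 5 of 84 splits gave as many probes (1, highest other 5790). Over all 84 splits chance thus cannot be excluded for this contrast. These splits ignore the experiments. The real one took 1 array of each experiment into the group of 3, and no other such split had a call. The 4 splits with more probes took at least 2 arrays from 1 experiment. The splits with 5790 and 1479 probes had the 2 arrays of experiment 1 in the group of 3, while the other 5 of the 7 splits with both in that group gave 0. The split with 43 set apart the 3 arrays of experiment 2 and the one with 130 the 3 r2 arrays, both with the arrays of experiment 1 in the group of 6. All 4 splits with more probes than the real one thus kept the arrays of experiment 1 together, as did splits with 0 probes. The split with 5790 held r2 replicate 3a, and with replicate 3b in its place the count was 0. Replicates 3a and 3b correlated with r = 0.991. The cause of the large counts was not tested.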

How the results depend on the processing

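Settings with normexp, with experiment 1 left out, and the combinations of the replicate block with other settings were chosen after the main counts were seen. The setting log2(value + 16) was the one of the design and became an alternative when, after the scale of the values was seen, the main fit was made without a pseudocount. Numbers below are probes or lists called, with higher and lower probes in parentheses where the split is given. The cause of each change was not tested. No probe called in the main fit was called in the opposite direction in any setting, and over 80 gene comparisons in the text, of 2238 values under other settings 1787 kept direction and side of the threshold, 418 kept the direction but did not pass, 33 passed where the main value had not, and 0 reversed.

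For Hoxb1a-deficient against normal r4 (0 probes) the count was 1 with log2(value + 16), log2(value + 64), array weights, an adjusted p under 0.1 or experiment 1 left out, 2 with the replicate block, 5 (2 higher, 3 lower) with the replicate block and quantile normalization, 9 (5, 4) with the experiment as a random block, 11 (5, 6) with the replicate block and a trended, robust eBayes, 0 with the replicate block and log2(value + 1) or experiment 1 left out, and 0 to 1 without single arrays.

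For r2 against r4 (94: 22, 72) it was 162 (54, 108) with quantile normalization, 149 (60, 89) with normexp and quantile normalization, 44 (17, 27) with log2(value + 1), 4 with log2(value + 16) or log2(value + 64), 41 (10, 31) with the 2 r2 samples of experiment 3 averaged, and 33 to 113 without single arrays. With the replicate block it was 276 (124, 152), with quantile normalization added 443 (211, 232), with a trended, robust eBayes 342 (156, 186), with log2(value + 1) 65 (21, 44), without experiment 1 118 (40, 78), and with a random block 358 (167, 191).

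For Hoxb1a-deficient r4 against r2 (90: 62, 28) it was 186 (109, 77) with quantile normalization, 162 (87, 75) with normexp and quantile normalization, 41 (22, 19) with log2(value + 1), 5 with log2(value + 16), 4 with log2(value + 64), 30 (21, 9) with the r2 samples averaged, and 27 to 113 without single arrays. With array weights it was 1168 (410, 758), where the weights did not converge fully. With the replicate block it was 359 (142, 217), with quantile normalization added 541 (267, 274), with a trended, robust eBayes 437 (185, 252), with log2(value + 1) 94 (43, 51), without experiment 1 147 (85, 62), and with a random block 428 (178, 250).

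For both tissues against r4 (4) it was 28 with quantile normalization, 24 with normexp and quantile normalization, 2 with log2(value + 1), 1 with log2(value + 16) or log2(value + 64), and 2 to 12 without single arrays. With the replicate block it was 67, with quantile normalization added 95, with a trended, robust eBayes 121, with log2(value + 1) 6, without experiment 1 3, and with a random block 115. Probes lower in both tissues (0) numbered 1 with the replicate block alone or with quantile normalization, a random block, array weights, log2(value + 16), log2(value + 64), an adjusted p under 0.1 or experiment 1 left out, 2 with the replicate block and a trended, robust eBayes, 0 with the replicate block and log2(value + 1) or experiment 1 left out, and 0 to 1 without single arrays. Probes higher in both (0) numbered 2 with a random block or with the replicate block and a trended, robust eBayes, and 1 with the replicate block and quantile normalization.

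For lists, Hoxb1a-deficient against normal r4 (0) gave 1 with dim probes left out and 0 to 8 without single arrays. The 9 lists of r2 against r4 became 2 with an estimated correlation, 4 with fry and 0 with the replicate block and an estimated correlation. The 9 lists of Hoxb1a-deficient r4 against r2 became 0, 5 and 0. With camera the replicate block changed no list calls other than those given beside their results. The heart genes, called as higher in r2 than in r4 by the main fit, were called so in 12 of 26 other settings and had the opposite direction, without a call, in 2, with array weights (adjusted p = 0.797) and with experiment 1 left out (0.98). No other list called by the main fit changed direction in a camera setting. The random block was not run for lists.

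With fry the replicate block ended the call on midbrain, isthmus and rhombomere 1 genes in r2 against r4 (adjusted p = 0.0127 to 0.061) and added cranial sensory ganglion (0.0361) and endothelial genes (0.00935). In Hoxb1a-deficient r4 against r2 it ended that on skin genes (0.0472 to 0.139) and added endothelial genes (0.0142). List members past the test with the replicate block and not without it were, in r2 against r4, 2 midbrain, 1 progenitor, 1 neurogenesis and 1 yolk and endoderm gene higher. Lower were 2 skin genes and 1 each of the r4, planar polarity, progenitor, neurogenesis, ganglion and immediate early genes. In Hoxb1a-deficient r4 against r2 they were 2 Hox, 2 r4, 2 skin and 1 each of the segment, retinoic acid, neural crest and eye genes higher. Lower were 4 neurogenesis, 3 progenitor, 2 Fgf target, 2 endothelial and 1 each of the midbrain, otic and reference genes.

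The probes at least 1.5-fold lower in each experiment (20) became 5 at 2-fold, 198 at 1.2-fold, 13 with log2(value + 1), 3 with log2(value + 16), 1 with log2(value + 64), 12 with normexp and quantile normalization, and 38 to 149 without 1 experiment. Those higher (8) became 4 at 2-fold, 78 at 1.2-fold, 17 with quantile normalization, 1 with log2(value + 16), 0 with log2(value + 64), 13 with normexp and quantile normalization, and 23 to 43 without 1 experiment. These counts are made within the pairs of an experiment, and probes 4651 and 4686 were the only ones of the 28 past the test with the replicate block. Signal over background limits folds at or below the array median, where pseudocounts shrink them.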

Other observations

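The value in this part was found by looking through single arrays after the comparisons were made. The cathepsin gene ctslb measured 73.8 in Hoxb1a-deficient r4 replicate 1 and 0.412 to 1.04 in the other 8 arrays: 0.412, 0.806 and 0.764 in normal r4 of experiments 1, 2 and 3, 0.815 and 0.676 in Hoxb1a-deficient r4 of experiments 2 and 3, and 0.715, 0.583 and 1.04 in normal r2 replicates 2, 3a and 3b. In Hoxb1a-deficient r4 replicate 1 the hatching gland genes he1.3 and klf17 measured 0.602 and 0.403.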
